A study of Homo sapiens with 6 samples.

How the data were processed

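The series holds 6 libraries of poly(A) RNA from HepG2, a human hepatocellular line, per the labels. All were treated with lipopolysaccharide at 1 µg/mL for 24 h, 3 as wild type and 3 titled FOXO1-KO, whose genotype field says FoxO1 knockdown. RNA was extracted with Trizol and messenger RNA captured on beads, per the labels' protocols. Whether the 3 replicates of a group were separate cultures is not stated, so p-values measure only the spread between these samples. Whether the libraries keep strand information is not stated either.

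The authors deposited a single table of 20323 genes. It gives whole-number read counts per library, per the file headers, and whether these are rounded RSEM estimates is not stated. The authors also deposited FPKM per library, a unit scaled for gene length and depth, with a mean FPKM per group that has a floor of 0.001. The deposited log2 ratio equals the log2 of the ratio of those means, FOXO1-KO over wild type, in all 20323 genes. The deposited p-value comes from a test that the authors do not name, and the deposited false discovery rate equals the Benjamini-Hochberg adjustment over the 15791 genes with at least 1 count. The tools fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, StringTie 1.3.1 and RSEM and the genome build GRCh38 were used, per the submitters' processing notes, which give no roles. Counts per gene sum reads over all exons, so an edited but transcribed copy of a gene still counts. Reads shared by near-identical genes can be assigned to the wrong copy, which concerns AKR1C, HLA, ribosomal protein and mitochondrial genes.

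Of the gene IDs, 20301 were found in a table of gene names and 20171 had GENCODE 29 coordinates on GRCh38. Of 169 genes without a symbol, 74 could be named. No count was seen for 4532 genes. Library totals ran from 14909695 to 21333863 counts, so 3 counts, taken as the floor per library, amount to 0.141 to 0.201 CPM (counts scaled to library size). Floors and bounds from it cover counting error only. ALB took the largest share of every library, from 4.59% to 5.47%.

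Counts were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with group as the only term. This left 12082 genes, and calls are at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.0895. CPM values are TMM-scaled, given as mean ± SD of 3 libraries, and fold changes are libraries labelled FOXO1-KO over wild type. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log CPM, adjusted over 25 lists. KEGG pathways of 10 to 300 tested genes, from the annotation of 8395 genes in the deposited table, were tested by a one-sided hypergeometric test per direction.

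The 25 lists, with 892 members in all of which 2 were not matched, were FOXO target genes, NF-kB response genes, cytokines and chemokines, acute-phase proteins, LPS and Toll-like receptor signalling, interferon-stimulated genes, and inflammasome and pyroptosis. Metabolic lists were gluconeogenesis and glycolysis, lipogenesis and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation and PPARA targets, hepatocyte identity, bile acid and drug metabolism, and complement and coagulation. Further lists were unfolded protein response, antioxidant and NRF2 target genes, cell cycle, p53 target genes, extracellular matrix, TGF-beta and EMT, hypoxia response, and autophagy and lysosome. Leukocyte markers and stellate, fibroblast and endothelial markers stood for other cell types, and mitochondrially encoded transcripts and immediate-early genes for RNA handling. The lists, the tests of genes, lists and pathways, the rule for named genes and the alternatives were fixed before the data were examined, except 4 alternatives named as chosen later. Gene groups and several tests under the other observations were also chosen later, as stated there.

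Genes are named by a rule. It takes the 4 FOXO genes, the 6 largest rises and 6 largest falls among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups. It adds the 2 members of each list with the smallest adjusted p, 11 genes of inflammation and FOXO1 function whatever their test, and 2 called members of each KEGG pathway discussed. Some genes that the rule takes are not reported here. Tests were tried on simulated counts drawn from these libraries. For the libraries labelled FOXO1-KO against wild type, edgeR was run on 11985 simulated genes. Of these, 67, 66 and 65 were changed 1.5-fold, 2-fold and 4-fold, with rises and falls in balance. The test recovered 62.7%, 93.9% and 100% of them, and 8.2% of its calls were false. Far more genes were called in the real data, so these rates need not hold there.

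Alternatives were DESeq2 size factors, total library size alone, no filter, a mean of at least 5 CPM, the Wald test of DESeq2 1.42.0 and limma on the deposited FPKM with pseudocounts of 1 or 0.1 and with or without a minimum mean FPKM of 0.5. Others were a replicate block, each library left out, stricter thresholds, a test against a fold of 1.2 and other list tests. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.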

Results

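Messenger RNA was measured by sequencing of poly(A) RNA from HepG2 cells, a human line derived from a liver tumour that keeps many hepatocyte functions. All 6 libraries came from cells given lipopolysaccharide (LPS), the bacterial cell-wall molecule that sets off innate immune signalling, at 1 µg/mL for 24 h. The 3 wild-type libraries held 17715043, 15558635 and 14909695 counts, and the 3 libraries labelled FOXO1-KO held 15386954, 17821326 and 21333863. The series title names the question, which is how loss of FOXO1 in hepatocytes bears on inflammation in metabolic dysfunction-associated steatohepatitis, a fatty liver disease. FOXO1 is a transcription factor that insulin signalling keeps out of the nucleus. No cells without LPS were analysed here, so every difference is between genotypes under LPS and none measures the response to LPS. The first principal component held 65.2% of the variance and set the 3 libraries of each group apart. Wild-type replicate 1 stood apart on the second component, with 14.1% of the variance, at 24.4 against -8.8 and -18.8 for the other wild-type libraries. Transcripts of the mitochondrial genome took 11.43%, 8.77% and 11.37% of the counts in the wild-type libraries and 7.14%, 8.21% and 7.04% in those labelled FOXO1-KO.

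FOXO1 RNA was not reduced. It was 1.3-fold higher in the libraries labelled FOXO1-KO, at 41.7 ± 0.471 CPM (read counts scaled to library size by TMM; SD, n = 3) against 32.0 ± 3.76 in wild type (SD, n = 3). The log2 difference was 0.38 with a standard error of 0.09 (edgeR, adjusted p = 0.00954). All 3 libraries labelled FOXO1-KO, at 42.2, 41.3 and 41.6 CPM, lay above the wild-type libraries, at 36.4, 29.5 and 30.2 CPM. The titles call these cells knockout while the genotype field calls them knockdown. Gene-level counts include RNA from an edited copy of the gene, and exon-level reads were not analysed here. The gene (ENSG00000150907) lies on chromosome 13 of GRCh38, from 40469953 to 40666597 on the minus strand. FOXO3, a related factor, had a log2 difference of -0.19 and did not pass (edgeR, adjusted p = 0.108). FOXO4 fell by 0.42 on the log2 scale (edgeR, adjusted p = 0.0425), a call that was lost at total library size (adjusted p = 0.141) and without each library except wild-type replicate 3 (adjusted p from 0.0751 to 0.145). FOXO6 had at most 1 count in any library.

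Several well-known targets of FOXO factors fell in the libraries labelled FOXO1-KO, although FOXO1 RNA itself did not. IGFBP1, a secreted binding protein of insulin-like growth factors, was 6.44-fold lower, at 387 ± 18.6 CPM against 2494 ± 134 (SD, n = 3 per group). G6PC1, which releases free glucose from the hepatocyte, was 10.9-fold lower, at 27.0 ± 4.49 against 294 ± 22.3 CPM. PCK1, an early enzyme of gluconeogenesis, was 7.41-fold lower, at 41.2 ± 4.12 against 305 ± 21.0 CPM. Adjusted p-values from edgeR were 9.74e-10 for IGFBP1, 8.56e-09 for G6PC1 and 1.21e-09 for PCK1. IRS2, which carries the insulin signal inside the cell, had 9, 7 and 4 counts in wild type and 0 in each library labelled FOXO1-KO. With 3 counts per library as the floor, IRS2 was at least 2.43-fold lower, with too few counts to be tested. Of the 33 FOXO target genes tested, 3 rose, 18 fell and 12 did not pass. Adjusted over the list alone, 5 rose and 21 fell. The list as a whole was lower than other genes (camera, adjusted p = 8.57e-08), with adjusted p = 0.0671 with an estimated correlation.

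**Figure D1:**
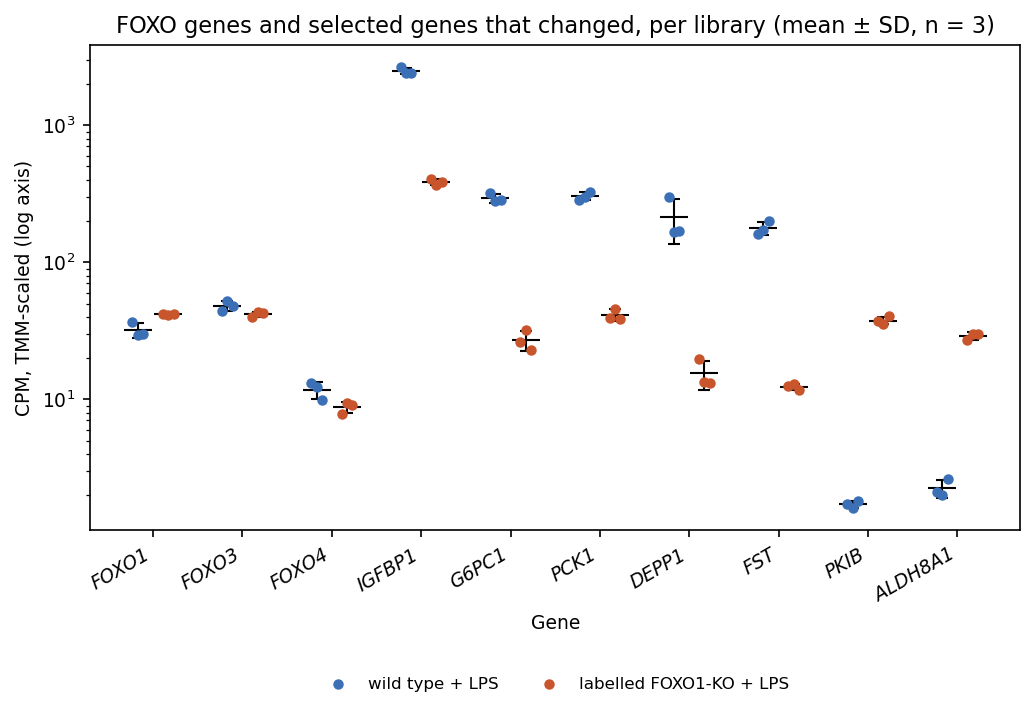
CPM on a log axis for FOXO genes and selected genes that changed, in each of the 6 libraries, with the mean and SD of each group (n = 3). FOXO1 was higher in the libraries labelled FOXO1-KO (41.7 against 32.0 CPM), while IGFBP1, G6PC1 and PCK1 were lower in all 3 of them.

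Across the genome, 12082 genes were tested and 3542 of them differed, 1699 higher and 1843 lower in the libraries labelled FOXO1-KO (edgeR). Among called genes with a mean of at least 5 CPM and no overlap between the groups, the 6 largest rises were those of PKIB, ALDH8A1, SHC3, RNF157, ERP27 and SLC6A14. PKIB, an inhibitor of protein kinase A on chromosome 6 (122471917 to 122726373), was 21.9-fold higher, at 37.6 ± 2.41 against 1.71 ± 0.097 CPM (SD, n = 3 per group). ALDH8A1, an aldehyde dehydrogenase, was 13-fold higher and SLC6A14, an amino acid transporter, 7.60-fold higher. Under the same limits the 6 largest falls were those of ADGRL2, ISM2, CCL16, SLC19A3, FST and DEPP1. ADGRL2, an adhesion receptor on chromosome 1 (81306160 to 81992436), was 34.6-fold lower, at 1.48 ± 0.26 against 51.4 ± 5.05 CPM. FST, which encodes the activin-binding protein follistatin, was 14.3-fold lower, SLC19A3, a thiamine transporter, 14.5-fold lower, and DEPP1, a FOXO-responsive gene, 13.8-fold lower. Changes of at least 2-fold were fewer, with 198 genes higher and 375 lower. The groups' libraries did not overlap at 45.1% of tested genes, where chance gives 10%. Scaling to total library size moved the median of all genes up by 0.15 on the log2 scale and turned the split into 3588 higher and 1115 lower, so 76.3% of calls were higher against 48% with TMM. Without wild-type replicate 1 there were 2058 higher and 2179 lower. Without replicate 2 labelled FOXO1-KO 1054 genes were higher, and without replicate 3 of that group 942 were higher and 1143 lower. Directions below are therefore relative to the median gene.

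Most genes of glucose use and of the hypoxia response fell. Of 34 glycolysis and gluconeogenesis genes tested, 2 rose, 26 fell and 6 did not pass, and adjusted over the list alone 2 rose and 28 fell. G6PC1 and PCK1, named above, had the smallest adjusted p. The list was lower than other genes (camera, adjusted p = 3.31e-12), with adjusted p = 0.242 with an estimated correlation. Of 29 hypoxia response genes, none rose, 21 fell and 8 did not pass, and 23 fell when adjusted over the list alone, and at total library size 1 rose and 19 fell. P4HA1, a collagen prolyl hydroxylase, was 2.26-fold lower, at 209 ± 0.562 against 473 ± 29.3 CPM (SD, n = 3 per group). SLC2A3, a glucose transporter, was 2.99-fold lower, at 97.9 ± 4.91 against 292 ± 39.9 CPM. The median hypoxia member changed by -0.50 on the log2 scale, and the list was lower than other genes (camera, adjusted p = 6.16e-13). This was the only one of the 25 lists whose call held with an estimated correlation (camera, adjusted p = 0.0469), and with its 15 members in no other list that test gave adjusted p = 0.0902. The mitochondrial share of counts given above was lower in the same libraries.

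Inflammatory genes moved in both directions. NFKBIA, the NF-kB inhibitor that NF-kB itself induces, was 1.33-fold higher in the libraries labelled FOXO1-KO, at 127 ± 13.1 against 95.3 ± 5.50 CPM (SD, n = 3 per group; edgeR, adjusted p = 0.00385). CXCL8, a neutrophil-attracting chemokine, was 2.79-fold higher at a low level, 2.04 ± 0.689 against 0.714 ± 0.221 CPM (edgeR, adjusted p = 0.0098). IL6 and CCL2 had no counts in any library, which allows up to 0.201 CPM in the shallowest library. TNF (at most 8 counts), IL1B and TLR4 (at most 2 counts each) were too low to be tested. TLR4 is the receptor that senses LPS. Of 31 NF-kB response genes tested, 8 rose, 4 fell and 19 did not pass, with the same counts adjusted over the list alone. SDC4, a cell-surface proteoglycan, was 1.52-fold higher and CEBPB, a transcription factor of the acute-phase response, 1.75-fold lower. That list did not differ from other genes (camera, adjusted p = 0.348). Of 35 LPS and Toll-like receptor signalling genes, 9 rose, 1 fell and 25 did not pass, and 10 rose and 1 fell adjusted over the list alone. CHUK, a kinase that frees NF-kB, was 1.54-fold higher and TRAF3, an adaptor whose call was lost on the deposited FPKM, 1.43-fold higher. Their list did not pass either (camera, adjusted p = 0.122), and passed when replicate 1 of both groups was left out (camera, adjusted p = 0.0353), a choice made after seeing the data.

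Among 18 cytokine and chemokine genes tested, 3 rose, 9 fell and 6 did not pass, and adjusted over the list alone 4 rose and 10 fell. CCL16, a chemokine made in liver, was 24.9-fold lower, at 0.567 ± 0.172 against 14.4 ± 2.45 CPM (SD, n = 3 per group). TNFSF10, a death-receptor ligand that is also on the FOXO list, was 2.1-fold lower. The list was lower than other genes (camera, adjusted p = 0.0159), with adjusted p = 0.282 with an estimated correlation. The call was also lost without the low-count filter (camera, adjusted p = 0.175) and 29 of the list's 47 members were not tested. Of 36 interferon-stimulated genes tested, 14 rose, 2 fell and 20 did not pass, with the same counts adjusted over the list alone. PARP9, an interferon-induced ADP-ribosyltransferase family member, was 2.05-fold higher, at 16.1 ± 1.07 against 7.87 ± 1.06 CPM. The list was higher than other genes (camera, adjusted p = 0.00274), with adjusted p = 0.242 with an estimated correlation.

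Secreted liver proteins of inflammation and clotting were mixed. Of 21 acute-phase genes tested, 5 rose, 7 fell and 9 did not pass, with the same counts adjusted over the list alone, and at total library size 7 rose and 4 fell. HPX, which binds haem in blood, was 4-fold higher, at 43.2 ± 2.43 against 10.8 ± 2.27 CPM (SD, n = 3 per group). SAA4, a constitutive serum amyloid A, was 1.85-fold higher. The median of the list was -0.10 (0.05 at total library size, 0.02 without wild-type replicate 1 and -0.23 without wild-type replicate 3) while its mean was 0.06 and its test pointed up, and it did not pass (camera, adjusted p = 0.918). Of 46 complement and coagulation genes, 11 rose, 13 fell and 22 did not pass, and adjusted over the list alone 11 rose and 15 fell, and at total library size 14 rose and 8 fell. C4BPA, a complement inhibitor, was 1.97-fold higher and CD55, a membrane complement regulator, 2.88-fold lower (camera for the list, adjusted p = 0.551). Of 16 inflammasome and pyroptosis genes, 3 rose, 3 fell and 10 did not pass, and adjusted over the list alone 3 rose and 4 fell. CASP1, the protease of the inflammasome, was 2.89-fold higher at 4.47 ± 0.211 against 1.55 ± 0.545 CPM. NLRP1, an inflammasome sensor, fell to the counting floor, with 3, 1 and 1 counts against 23, 22 and 11 in wild type (edgeR, adjusted p = 0.00066), so no fold is given. The list's median was 0.04 (0.18 at total library size, -0.02 with GC-corrected offsets chosen after seeing the data, and from -0.03 to 0.06 without each library, below 0 without wild-type replicate 1 or 2) while its mean, with the fitted value of NLRP1, was -0.30, and it did not differ from other genes (camera, adjusted p = 0.918).

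**Figure D2:**
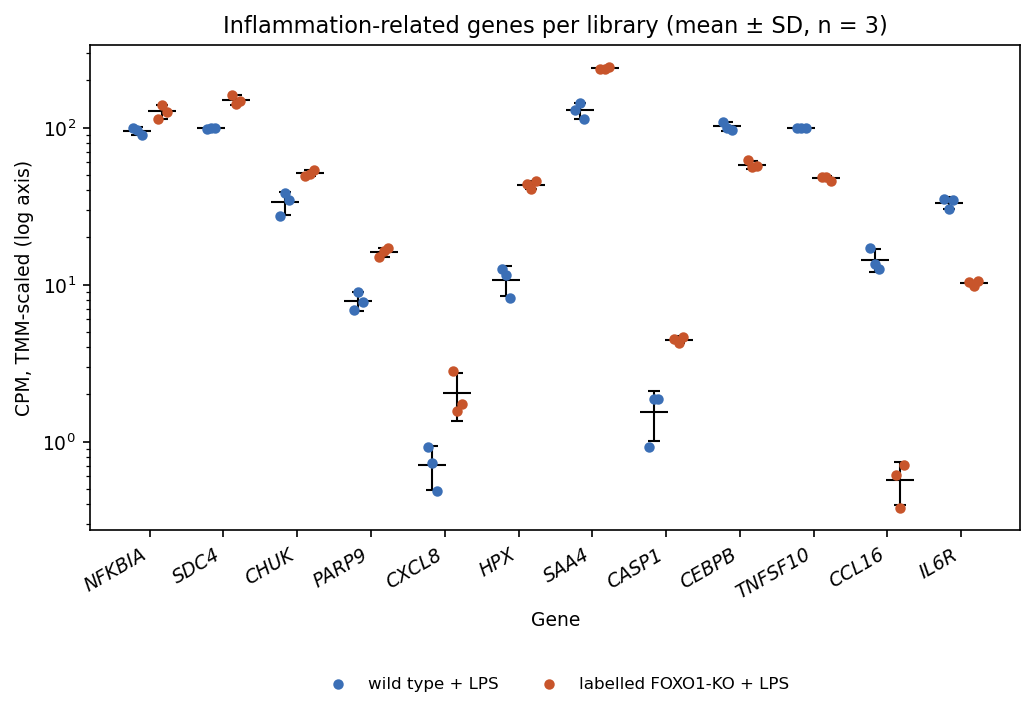
CPM on a log axis for 12 inflammation-related genes in each of the 6 libraries, with the mean and SD of each group (n = 3). NFKBIA, SDC4, CHUK, PARP9, CXCL8, HPX, SAA4 and CASP1 were higher in the libraries labelled FOXO1-KO, and CEBPB, TNFSF10, CCL16 and IL6R lower.

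Among cholesterol synthesis genes that passed, more rose than fell, and among fatty acid oxidation genes more fell than rose. Of 25 cholesterol synthesis genes, 9 rose, 2 fell and 14 did not pass, and adjusted over the list alone 10 rose and 3 fell, and at total library size 16 rose and 1 fell. HMGCS1, which makes the precursor of mevalonate, was 1.56-fold higher, at 982 ± 38.5 against 628 ± 49.5 CPM (SD, n = 3 per group), and IDI1, a later enzyme of the pathway, 1.72-fold higher. The list was higher than other genes (camera, adjusted p = 0.0305), with adjusted p = 0.262 with an estimated correlation. Its call was lost without wild-type replicate 3 (adjusted p = 0.0747) and without replicate 1 of the group labelled FOXO1-KO (adjusted p = 0.0548). Of 30 genes of fatty acid oxidation and PPARA response, 5 rose, 12 fell and 13 did not pass, and adjusted over the list alone 5 rose and 13 fell, and at total library size 9 rose and 9 fell. ACSL1, which activates fatty acids, was among those that rose, 2.32-fold higher at 88.6 ± 3.22 against 38.2 ± 4.66 CPM. The list was lower than other genes (camera, adjusted p = 0.0223), with adjusted p = 0.242 with an estimated correlation. That call was lost on the deposited FPKM (limma values, camera adjusted p = 0.0525).

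Lipogenesis genes were split, with 7 rising, 10 falling and 16 of 33 not passing, and adjusted over the list alone 9 rose and 10 fell, and at total library size 13 rose and 5 fell. DGAT2, which completes triglycerides, was 1.60-fold higher, and FADS2, a fatty acid desaturase, 3.19-fold lower, at 53.7 ± 2.62 against 171 ± 30.5 CPM (SD, n = 3 per group; camera for the list, adjusted p = 0.918). Of 28 bile acid and drug metabolism genes, 5 rose, 13 fell and 10 did not pass, with the same counts adjusted over the list alone. ABCG2, an efflux pump, was 3.39-fold lower and BAAT, which conjugates bile acids, 2.51-fold lower. The list was lower than other genes (camera, adjusted p = 0.0358), with adjusted p = 0.242 with an estimated correlation. Leaving out wild-type replicate 2 (adjusted p = 0.0850), wild-type replicate 1 (0.0575) or replicate 1 labelled FOXO1-KO (0.0554) ended that call, as did a filter at a mean of 5 CPM (0.0822). Of 36 hepatocyte identity genes, 5 rose, 12 fell and 19 did not pass, and adjusted over the list alone 6 rose and 14 fell, and at total library size 14 rose and 8 fell. AFP, the fetal albumin-like protein that HepG2 makes in quantity, was 1.87-fold lower and APOA4, an apolipoprotein, 3-fold lower. The hepatocyte list did not pass (camera, adjusted p = 0.112), and passed without wild-type replicate 3 (camera, adjusted p = 0.0154).

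ASNS, asparagine synthetase, was 5-fold lower in the libraries labelled FOXO1-KO, at 20.4 ± 3.83 against 102 ± 4.38 CPM (SD, n = 3 per group). VLDLR, a lipoprotein receptor, was 4.36-fold lower. Both are on the unfolded protein response list, of which 4 rose, 13 fell and 14 of 31 did not pass, and adjusted over the list alone 4 rose and 14 fell, and at total library size 8 rose and 10 fell, with a median of -0.08 against -0.23. The list was lower than other genes (camera, adjusted p = 0.00284), with adjusted p = 0.262 with an estimated correlation. SLC7A11, the cystine importer, was 6.23-fold lower, at 12.5 ± 1.23 against 78.1 ± 15.7 CPM, and AKR1C3, one of several near-identical reductases, 2.24-fold lower. Of 38 antioxidant and NRF2 target genes, 5 rose, 14 fell and 19 did not pass, and adjusted over the list alone 7 rose and 14 fell. Their median was -0.14 and turned to 0.01 at total library size, where 14 rose and 10 fell. The list was lower than other genes (camera, adjusted p = 0.0177), with adjusted p = 0.262 with an estimated correlation and 0.0528 at total library size. Immediate-early genes, included as a sign of RNA handling, moved with the groups. Of 23 tested, 1 rose, 9 fell and 13 did not pass, and adjusted over the list alone 1 rose and 10 fell. DUSP6, a phosphatase induced by growth signals, was 2.09-fold lower, and the growth regulator MYC 1.83-fold lower. Their list was lower than other genes (camera, adjusted p = 0.00284), with adjusted p = 0.262 with an estimated correlation. Of 44 autophagy and lysosome genes, 5 rose, 13 fell and 26 did not pass, and adjusted over the list alone 6 rose and 13 fell, and at total library size 12 rose and 5 fell. CTSB, a lysosomal protease, was 1.91-fold lower and NBR1, an autophagy receptor, 1.62-fold lower (camera for the list, adjusted p = 0.226).

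Among cell cycle genes and p53 targets that passed, most rose. Of 44 cell cycle genes, 23 rose, 1 fell and 20 did not pass, and adjusted over the list alone 25 rose and 1 fell. RRM2, which makes DNA precursors, was 1.59-fold higher, at 221 ± 14.6 against 139 ± 5.56 CPM (SD, n = 3 per group), and TYMS, thymidylate synthase, 1.48-fold higher. The list was higher than other genes (camera, adjusted p = 1.99e-06), with adjusted p = 0.257 with an estimated correlation. Of 35 p53 target genes, 20 rose, 3 fell and 12 did not pass, and adjusted over the list alone 22 rose and 3 fell. TIGAR, a regulator of glycolysis, was 2.28-fold higher, at 17.2 ± 1.05 against 7.53 ± 0.125 CPM. PHLDA3, an inhibitor of AKT, was 1.87-fold higher. The list was higher than other genes (camera, adjusted p = 2.2e-05), with adjusted p = 0.242 with an estimated correlation.

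Matrix genes were split, with 9 rising, 11 falling and 12 of 32 not passing, and adjusted over the list alone 9 rose and 13 fell, and at total library size 11 rose and 7 fell. SPARC, a matrix-binding glycoprotein, was 4.09-fold higher, at 74.2 ± 6.83 against 18.1 ± 1.64 CPM (SD, n = 3 per group), and THBS1, thrombospondin 1, 2.90-fold higher. The extracellular matrix, TGF-beta and EMT list did not differ from other genes (camera, adjusted p = 0.918), and its mean of 0.04 and its test, which pointed down, differed in sign. Marker genes of other liver cell types were mostly too low to test, 20 of 30 for leukocytes and 18 of 25 for stellate, fibroblast and endothelial cells. PTPRC, the pan-leukocyte gene, had none. Of 10 leukocyte markers tested, none rose, 5 fell and 5 did not pass, and 6 fell adjusted over the list alone. LYZ, lysozyme, which HepG2 cells carried at 2121 ± 115 against 3089 ± 122 CPM, was 1.46-fold lower. The leukocyte list was lower than other genes (camera, adjusted p = 0.0159), with adjusted p = 0.307 with an estimated correlation and 0.0929 without wild-type replicate 1. Of 7 stellate, fibroblast and endothelial markers tested, 2 rose, 3 fell and 2 did not pass, and adjusted over the list alone 2 rose and 4 fell. TAGLN, an actin-binding protein, was 2.74-fold higher and PDGFRB, a growth factor receptor, 3.62-fold lower (camera for the list, adjusted p = 0.542). Mitochondrially encoded transcripts, the other sign of RNA handling, moved with the groups as well. Of 13 tested, none rose, 8 fell and 5 did not pass, and 12 fell adjusted over the list alone. MT-ND4, a subunit of complex I, was 1.81-fold lower, at 9178 ± 1184 against 16613 ± 2769 CPM, and MT-CO1, a subunit of complex IV, 1.65-fold lower, with nuclear copies a source of uncertainty. The mitochondrial list was lower than other genes (camera, adjusted p = 2.55e-05), with adjusted p = 0.307 with an estimated correlation.

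**Figure D3:**
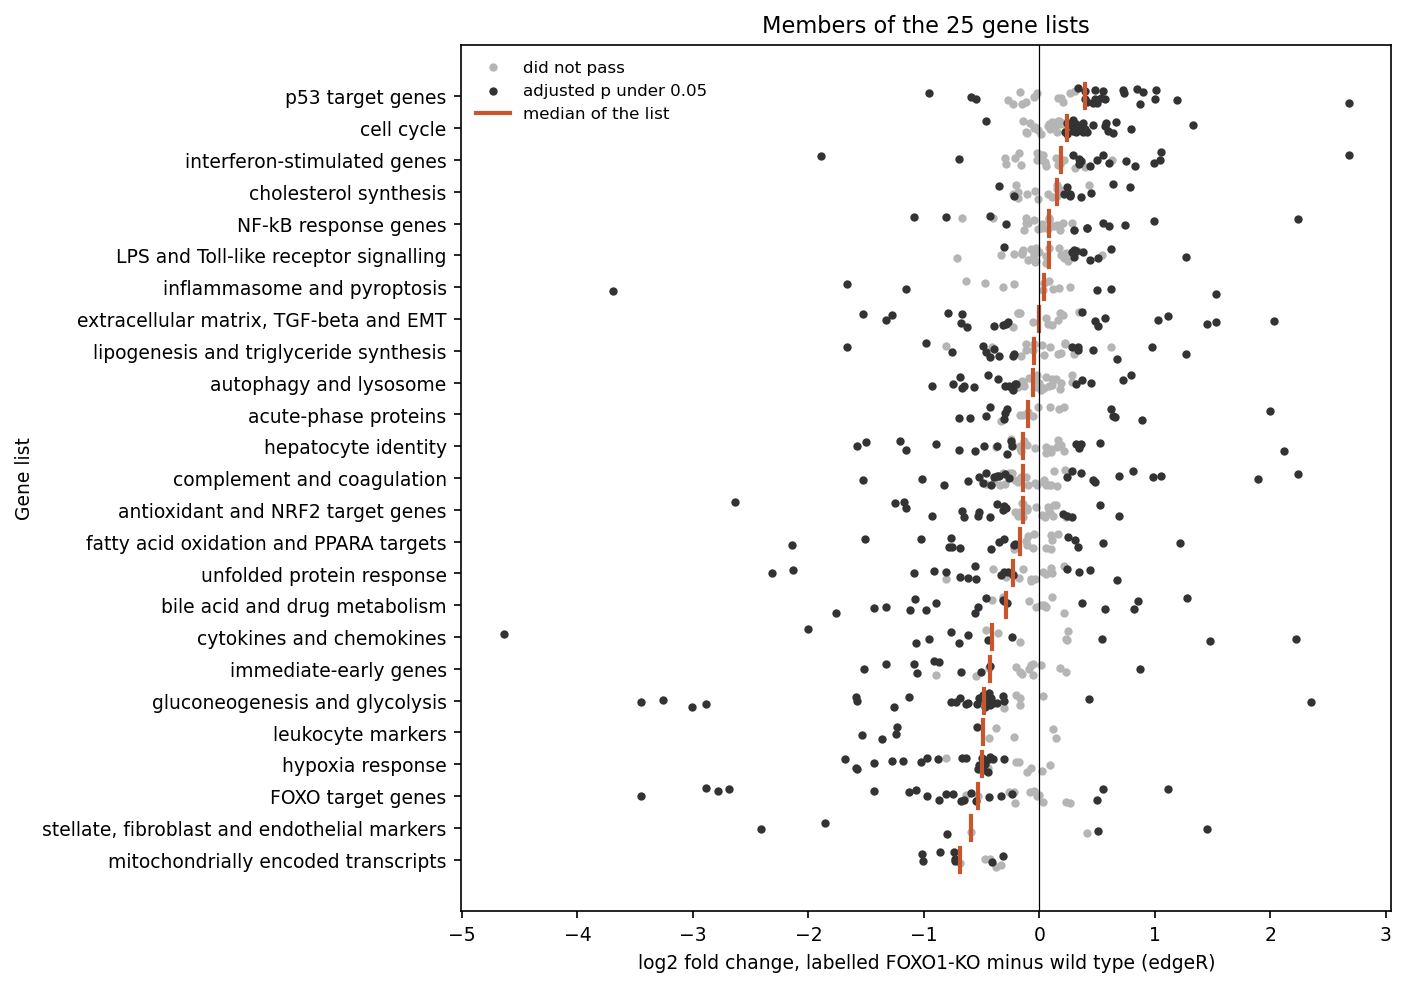
Log2 fold changes (libraries labelled FOXO1-KO minus wild type, edgeR) of every tested member of the 25 gene lists, with dark points for members at adjusted p under 0.05 and a bar at each list's median. Medians run from -0.69 for mitochondrially encoded transcripts to 0.39 for p53 target genes, and no hypoxia response gene rose with TMM (1 at total library size).

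Of 314 KEGG pathways tested, 15 were enriched among genes that fell. Biosynthesis of amino acids held 33 called genes of 66 tested, 2.85 times the number expected (hypergeometric test, adjusted p = 4.21e-07), with ASNS 5-fold lower and GPT2, a transaminase, 1.88-fold lower. PPAR signaling held 28 of 56 (adjusted p = 1.91e-06), with PCK1 and FADS2, both described above, among its members. Ribosome held 50 of 133 (adjusted p = 1.91e-06), with RPL8 1.48-fold and RPL18 1.43-fold lower, values that near-identical pseudogene copies leave uncertain. Aminoacyl-tRNA biosynthesis held 17 of 44 (adjusted p = 0.0177), with GARS1 and CARS1, which charge glycine and cysteine tRNAs, 1.92-fold and 1.90-fold lower. HIF-1 signaling held 27 of 83 (adjusted p = 0.0171), with the growth factor receptor EGFR 3.84-fold lower and IL6R, a subunit of the interleukin 6 receptor, 3.25-fold lower at 10.2 ± 0.353 against 33.3 ± 2.78 CPM (SD, n = 3 per group). Coronavirus disease - COVID-19 held 63 of 182 (adjusted p = 1.91e-06), EGFR and IL6R among them. Its overlap with Ribosome and the other pathways was not counted, so it is not a separate result. PI3K-Akt signaling was enriched among genes that fell (56 of 212, adjusted p = 0.0171) and among genes that rose (46 of 212, adjusted p = 0.0471). Among genes that rose, 36 pathways were enriched, many of them named for viral infections or cancers. The p53 signaling pathway held 26 of 65 (adjusted p = 8.25e-05), with AIFM2, a p53-induced oxidoreductase, 1.60-fold higher and THBS1 2.90-fold higher. DNA replication held 15 of 38 (adjusted p = 0.00362), with RPA2 1.65-fold and FEN1 1.63-fold higher. Antigen processing and presentation held 15 of 41 (adjusted p = 0.00721), with CTSS, a lysosomal protease, 3.05-fold and the proteasome activator PSME3 1.44-fold higher. With calls limited to changes of at least 2-fold, 4 pathways among genes that rose and 5 among genes that fell passed. The 36 became 21 without wild-type replicate 2, 17 without wild-type replicate 3 and 21 without replicate 3 labelled FOXO1-KO.

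The authors' deposited table of the same comparison listed 3157 genes at a false discovery rate under 0.05, of which 1449 were higher and 1708 lower in the libraries labelled FOXO1-KO. Of these, 3027 were also called here in the same direction, 8 were called here in the opposite direction and 60 were not tested here. The rest were tested but not called here, and their direction was not counted. Over genes called in both, the log2 change here was lower than in the authors' deposited table by a median difference of -0.15. The deposited ratios rest on FPKM, and the median gene here moved up by 0.14 to 0.15 with limma on FPKM. The authors' deposited table gave FOXO1 a mean FPKM of 7.59 in the libraries labelled FOXO1-KO and 5.25 in wild type (deposited false discovery rate 0.00767).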

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

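Tests chosen only after the data were seen are the GC-corrected offsets, leaving out number 1 of both groups, and the lists limited to members in no other list, with a preset or an estimated correlation. FOXO1 was higher and called in each alternative run for it, with log2 differences from 0.32 to 0.53 and adjusted p from 6.96e-05 to 0.0497. None of the tested genes reported by the naming rule changed direction in any alternative, and FOXO4 and TRAF3 were among those that lost their calls in some. Calls shared with the TMM result had the same direction in every setting. The libraries hold 14909695 to 21333863 counts, so genes under about 0.2 CPM lay below the floor of 3 counts. The filter also left out genes above that floor, such as IRS2 at 0.433 CPM in wild type. Of the 47 cytokines and chemokines listed, 29 were not tested. Where a value below changes, the cause was not tested, except that stricter thresholds call fewer genes by construction.

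Genes higher and lower numbered 1699 and 1843. They became 3588 and 1115 at total library size, where the median gene moved by 0.15 and 76.3% of calls were higher against 48%. On log2(FPKM + 1) they were 2763 and 914 (75.1% higher), on log2(FPKM + 0.1) 2744 and 913 (75% higher), and on unfiltered FPKM 2293 and 894 (71.9% higher), with median shifts of 0.14 to 0.15. Thresholds gave 198 and 375 at a log2 fold of at least 1, 887 and 1105 at adjusted p under 0.01, and 583 and 856 against a fold of 1.2. Without each library the counts ran from 942 to 2058 higher and from 1143 to 2179 lower, lowest without replicate 3 labelled FOXO1-KO, and 1054 were higher without replicate 2 of that group. The replicate number as a block gave 2033 and 2140. Whether the numbers pair the libraries is not stated. Deviations correlated at 0.18, 0.08 and 0.14 within numbers and at most at 0.05 across them. All 6 libraries correlated best with their own number, a weak hint of pairing that the main fit left out. Deviations were taken from each group's mean, so the 6 matches are not independent of one another, and how often chance gives them was not tested. KEGG pathways among higher genes ran from 17 to 45 without each library, and with a log2 fold of at least 1 there were 4 higher and 5 lower. With that threshold 438 calls were shared with the authors' table.

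With an estimated correlation adjusted p was 0.0671 for FOXO targets, 0.282 for cytokines, 0.257 for cell cycle, 0.307 for leukocyte markers and mitochondrial transcripts, 0.262 for cholesterol synthesis, unfolded protein response, NRF2 targets and immediate-early genes, and 0.242 for interferon-stimulated, glycolysis, fatty acid oxidation, bile acid and p53 lists. Camera on ranks gave 0.0578 for cytokines, 0.0506 for cholesterol synthesis and fatty acid oxidation, and 0.0602 for bile acid and NRF2 lists, and turned acute-phase genes (0.836). The directional fry test called NF-kB and Toll-like receptor lists (both 0.0305) and turned the matrix list (0.348). Both fry tests, directional and mixed, ask whether a list's own members changed, not whether the list differed from other genes. The mixed test takes changes in either direction, and every list passed it. Its highest adjusted p was 0.0143, for mitochondrial transcripts, so it singles out no list and does not bear on the camera results. The mixed fry test gave 8.93e-06 for NF-kB, 7.92e-06 for acute-phase, 6.59e-05 for Toll-like receptor, 1.72e-05 for inflammasome, 8.41e-06 for lipogenesis, 0.000115 for hepatocyte, 2.7e-05 for complement, 1.59e-05 for matrix, 3.85e-05 for autophagy and 9.45e-06 for stellate lists.

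At total library size NRF2 targets had adjusted p = 0.0528 and acute-phase genes turned (0.929). On log2(FPKM + 1) and log2(FPKM + 0.1), acute-phase (0.776, 0.789), inflammasome (0.566, 0.576) and lipogenesis (0.996, 0.988) lists turned and fatty acid oxidation lost its call (0.0525, 0.0524). On unfiltered FPKM the values were 0.0667 for cytokines, 0.129 for fatty acid oxidation and 0.177 for NRF2 targets, and lipogenesis (0.743) and complement (0.958) turned. Without a count filter cytokines had 0.175 and stellate markers turned (0.974). With a mean of at least 5 CPM bile acid genes had 0.0822 and inflammasome genes turned (0.865). GC-corrected offsets turned lipogenesis (0.916) and matrix (0.922) lists. Leaving out number 1 of both groups gave 0.0353 for Toll-like receptor and 0.0747 for bile acid lists and turned lipogenesis (0.774) and matrix (0.740). With members in no other list, cytokines had 0.196, bile acid genes 0.0602 and stellate markers 0.0132, and inflammasome (0.939), lipogenesis (0.993) and matrix (0.795) lists turned. With those members and an estimated correlation, FOXO target and hypoxia lists had adjusted p = 0.0902, cytokines 0.499 and each other list called at the preset correlation 0.291, and inflammasome (0.939), lipogenesis (0.996) and matrix (0.885) lists turned.

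Without each library in turn, adjusted p ran from 0.458 to 0.988 for acute-phase, 0.724 to 0.988 for inflammasome, 0.657 to 0.988 for lipogenesis and 0.601 to 0.988 for matrix lists, which turned in some of these fits. It ran from 0.00935 to 0.0747 for cholesterol synthesis (0.0747 without wild-type replicate 3, 0.0548 without replicate 1 labelled FOXO1-KO), 0.0154 to 0.449 for hepatocyte identity (0.0154 without wild-type replicate 3) and 0.00266 to 0.0929 for leukocyte markers (0.0929 without wild-type replicate 1). For bile acid genes it ran from 0.0183 to 0.0850, with 0.0575 without wild-type replicate 1, 0.0850 without wild-type replicate 2 and 0.0554 without replicate 1 labelled FOXO1-KO.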

Other observations

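The tests of FOXO1 RNA, of the hypoxia list under other scalings, of the ATF4 branch, of estimated correlations for members in no other list and of the splits were chosen only after their results were seen, and the gene groups in this part were chosen after their values were seen. Changes here are in the libraries labelled FOXO1-KO, whose FOXO1 RNA was higher than in wild type. Looked at without an enrichment test were 18 genes of serine, glycine and one-carbon metabolism and of amino acid supply, ASNS and SLC7A11 among them. Of these 2 rose, 14 fell and 2 did not pass, with a median log2 change of -0.56. At total library size 4 rose and 10 fell, with a median of -0.41. ALDH1L2, a mitochondrial folate enzyme, changed by -3.95, MTHFD2 by -1.03 and SHMT2, which interconverts serine and glycine, by -0.80. Of 81 ribosomal protein genes, 1 rose, 45 fell and 35 did not pass, with a median of -0.24. At total library size 1 rose and 24 fell, with a median of -0.09. Among 6 insulin-like growth factor binding proteins, IGFBP2 (-4.34) and IGFBP3 (-3.73) fell alongside IGFBP1, while IGFBP4 (1.22) and IGFBP7 (2.63) rose. IGFBP2 and ALDH1L2 changed more than DEPP1 (-3.79) but are not among the 6 largest falls named above. They therefore did not meet both limits set there, a mean of at least 5 CPM and no overlap between the groups.

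FOXO1 RNA was higher in the libraries labelled FOXO1-KO while FOXO targets as a list were lower. An exchange of the 2 groups' labels would put FOXO targets higher in these libraries. The targets in no other list had a median of -0.39 with a spread of 0.15, which argues against it. Camera gave them adjusted p = 1.57e-05 at the preset correlation and adjusted p = 0.0902 with an estimated correlation. Spreads in this part are SDs over resampled member genes, and permutations shuffle genes. Neither resamples libraries, so both treat genes as independent. GC-corrected offsets gave FOXO1 a log2 difference of 0.37 (edgeR, adjusted p = 0.00498), which argues against GC content. DESeq2 size factors also gave 0.37, the lowest under the scaling, FPKM and GC settings. The highest adjusted p under these was 0.0117 (limma on unfiltered FPKM). Total library size and FPKM shift the median gene up by 0.14 to 0.15, so they could only raise the FOXO1 difference and do not test scaling. What sets the FOXO1 RNA level stays open, since neither exon-level reads nor FOXO1 protein were analysed here.

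Hypoxia response genes were lower together. Sharing members with the glycolysis and other lists is not enough to account for it, since the 15 members in no other list had a median of -0.45 (camera, adjusted p = 1.57e-05, and adjusted p = 0.0902 with an estimated correlation). Under other scalings, FPKM or GC correction the highest median was -0.35 with a spread of 0.09. With GC-corrected offsets the median was thus no higher than -0.35, which argues against GC content. Total library size and FPKM shift all genes by up to 0.15. A shift of that size does not account for the median of -0.50 with TMM, but it does not test the set against the median gene. No biological explanation was tested, and any difference between the cultures of the 2 groups other than FOXO1 is confounded with the label.

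Cytosolic tRNA synthetase genes were lower, with 11 of 20 falling, none rising and a median of -0.31 (10 falling, 3 rising and -0.16 at total library size), against a median of -0.08 (0.07 at total library size) for 17 mitochondrial ones. The difference of medians was -0.23 with a spread of 0.14 (permutation across genes, p = 0.031), which met the limits set before that test. A further demand, that the difference pass its limit by more than its spread, was not met. A fall shared by both sets therefore cannot be told apart from one of the cytosolic set. Scaling cannot be told apart from a fall in level either. The highest median of the cytosolic set under other scalings, FPKM or GC correction was -0.13 with a spread of 0.10. Total library size and FPKM shift all genes by up to 0.15, so this does not test the set against the median gene. GC-corrected offsets alone left the median at -0.30. Whether a weaker programme of ATF4, the factor of the amino acid response, plays a part also stays open, because the ATF4 branch of the unfolded protein response list, at a median difference of -0.71 from its other members (permutation p = 9e-04), was drawn up after its values were seen and holds ASNS and VLDLR. Of its 9 members tested 7 fell, ATF4 (-0.62) among them, and none rose, with 7 falling at total library size, while TRIB3 (-0.04, and 0.11 at total library size) and DDIT4 (-0.81) did not pass.

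The split of the 6 libraries into the 2 groups called 3542 genes and the highest of the other splits called 0, where 1 of 10 splits reached the real value and 10 splits are too few for a share under 0.05.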
